A study of Homo sapiens and Mus musculus with 81 samples.

How the data were processed

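RNA was measured in 81 samples: human H1 cells and mouse EpiSC, each sampled over days in vitro and as teratomas. Per the labels' protocols, cells in vitro were kept in a DF3S medium with N2, B27 and Noggin. For teratomas, per the same protocols, EGFP-positive cells were injected with Matrigel, and the tumours were dissected, digested with Dispase and Collagenase and sorted by flow cytometry. Lysates were stored frozen and processed in parallel with an RNeasy kit and the LM-Seq library method, per the labels' protocols. The host animal is not given in the sources used here, and reads of host cells that passed the sort were not separated from those of the graft in either species. Expected counts per gene were deposited by the authors with no further scaling recorded, made with CASAVA 1.8.2, Bowtie 0.12.9 and RSEM 1.2.3 and the builds hg19 and mm10 per the submitters' processing notes, which give neither the role of each tool nor the gene annotation. TPM values (each library scaled to a fixed sum and for transcript length) were deposited by the authors beside the expected counts and made with the same tools per the submitters' processing notes. The 8 deposited tables list 19097 genes for human and 20321 for mouse cells in vitro, and 19084 and 20308 for human and mouse teratomas, by gene symbol. In the expected count tables, 20.5% and 15.0% of the values were not whole numbers for human and mouse cells in vitro, and 28.9% and 25.6% for human and mouse teratomas. Expected counts were rounded to whole numbers for the tests. TPM values were used for levels, for timing and for 1 alternative test.

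Samples were grouped by species, setting and day. Human cells in vitro were sampled on 26 days, 16 of them up to day 21, and mouse cells in vitro on the same 16 days. The day 0 library of mouse cells in vitro is labelled as sorted, and no other library in vitro is. By their titles the human cells in vitro were H1Rosa7 and the mouse cells in vitro mEpi3 on days 0 and 1 and mEpi from day 2. The teratoma titles name only the species, and the cell type labels are H1 and EpiSC in both settings apart from 1 column described below. Human teratomas were sampled on 13 days, 9 of them up to day 21, and mouse teratomas on 12 days. On 8 human and 3 mouse teratoma days more than 1 column with the same day was present. These differed by little more than counting noise, so their counts were summed and their TPM averaged. This departs from the design fixed before the data were examined, which counted every column as a library, and the fit with separate columns is given as an alternative. In the labels of 1 human teratoma column of day 28 the cell type says EpiSC while title, description and organism say human. Its counts match the other column of that day, and it was used as human. Median totals per day were 1.76 M counts for human and 2.62 M counts for mouse cells in vitro, and 15.1 and 6.79 M counts for human and mouse teratomas. At these depths 3 counts correspond to 1.18 CPM on day 0 for human and 0.983 CPM for mouse cells in vitro, and to 0.146 and 0.431 CPM for human and mouse teratomas. Where a gene had no count on 1 of the compared days, the change is given as a bound against 3 counts in that day's library. Such bounds cover counting error only.

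Tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM scaling) with a natural cubic spline of day, inner knots at days 4 and 10, over days 0 to 21. Genes needed at least 10 counts in at least 3 libraries. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 with a fitted log2 range of at least 1, and its direction was that of the larger departure from day 0. Fitted differences of days 8 and 21 from day 0 were tested in the same fit. For human courses the fit to day 42 had 4 spline terms, and the difference of day 42 from day 21 was tested with a log2 change of at least 1. Courses were compared pairwise by 3 course-by-spline terms in a joint fit, over genes joined by identical symbol in upper case, with a fitted difference of at least 1. For this 15118 symbols were shared between the species in each setting, 19084 between the human settings and 20304 between the mouse settings. The biological coefficient of variation around the trend was 27.1% and 31.0% for human and mouse cells in vitro and 52.8% and 49.1% for human and mouse teratomas.

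The timing of shared genes was measured on log2(TPM + 1) with a running mean of 3 points. For genes called in the same direction in both courses with a move of at least 1, the first crossing of the midpoint between day 0 and the extreme within 21 days was interpolated. A time factor from 0.5 to 4 in steps of 0.05 was chosen by the highest Pearson correlation between mouse changes and interpolated human changes. It used at least 6 mouse days and human days to 42. The 22 gene lists (pluripotency, neural progenitor, early neuron, synapse, forebrain patterning, midbrain with hindbrain and HOX, retina, astrocyte and radial glia, oligodendrocyte, neural crest, mesoderm, muscle, cartilage and bone, mesenchyme and matrix, endoderm, epithelium, endothelium, blood, cell cycle, dissociation and stress, hypoxia and glycolysis, cholesterol synthesis) were tested with limma's camera (3.58.1) on log2 CPM, preset correlation 0.01, adjusted over the lists of a course. Members were counted as risen or fallen at an adjusted p under 0.05 on day 21, without a minimum change. Some genes are in 2 lists, for example SIX3, SOX9 and PDGFRA.

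The lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined. The rule names 28 key genes, the 5 largest rises and falls on day 21 per course with an average log2 CPM of at least 3, and up to 4 members of each list with the largest called change. It also names the 5 latest and 3 earliest genes in human per setting with at least 10 TPM in both species, and the 5 genes with the smallest p per pair of courses. The text prints part of them, and some genes that the rule names are not reported here. The genes of the day 42 comparisons other than key genes, and single days beside days 0, 8 and 21, were chosen after the values were seen. Alternatives were DESeq2 1.42.0 size factors and tests, limma on log2(TPM + 1) and log2(TPM + 0.1), other filters, 1 inner knot at day 8 or knots at days 3, 8 and 14, no minimum change, each day left out, and a block for the repeat number. For timing they were another pseudocount, linear TPM, no running mean, the spline curve, the day of the extreme, the whole human course, only highly expressed genes, rank correlation, root mean square difference and all expressed genes. For lists they were an estimated correlation and fry. Separate repeat columns, only shared days between the species, mouse days to 10 at every factor, and leaving out mouse teratoma day 16 were added after the data were seen.

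The tests were checked on simulated data with 200 changed genes per course. For a log2 change of 4 the edgeR test recovered 84.4% in human cells in vitro (12250 genes simulated), 93.7% in mouse cells in vitro (12595), 56.5% in human teratomas (13929) and 54.7% in mouse teratomas (13842). For a log2 change of 2 it recovered 67.7%, 70.1%, 29.7% and 7.9%. For a log2 change of 1 it recovered 10.4% and 7.8% in human and mouse cells in vitro, so that changes of this size were mostly not detectable in any course. Intervals of single genes within a day and variation between repeated courses could not be estimated, since 1 course per species and setting was analysed. Figures were drawn with matplotlib 3.10.9, and timing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Reads were not analysed here.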

Results

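Gene expression was followed by RNA sequencing in 81 libraries (50 human, 31 mouse) from 4 time courses of pluripotent cells. The human cells were H1, an established embryonic stem cell line, and the mouse cells were epiblast stem cells (EpiSC), which are derived from the post-implantation epiblast. Both were differentiated in vitro in a neural medium with Noggin, an inhibitor of BMP signalling, and both were also grown as teratomas from EGFP-positive cells that were dissociated and sorted again. The question the series addresses is whether the pace of differentiation differs between the species, and whether a difference seen in culture is also seen in teratomas. Total expected counts (in M, mega) were 0.909 to 3.32 per library for human cells in vitro (26 libraries, days 0 to 42) and 1.93 to 3.10 for mouse cells in vitro (16 libraries, days 0 to 21). They were 3.34 to 13.3 per column for human teratomas (24 columns from 13 days, to day 42) and 4.69 to 10.4 for mouse teratomas (15 columns from 12 days, to day 21). The 17 pairs of repeat columns of 1 teratoma day differed by 1.18 to 1.39 times the variance of counting noise, against 6.66 to 156 times between neighbouring teratoma days, so the columns of a day were counted as 1 sample. There was 1 course per species and setting, and the p-values measure the scatter of days around 1 smooth trend per course, not the variation between repeated courses. Values after ± are standard errors, adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named, and n is the number of days.

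In human H1 cells in vitro, pluripotency genes fell and neural progenitor, forebrain and neuron genes rose over 21 days (n = 16). POU5F1, a core pluripotency transcription factor, went from 1925 TPM on day 0 to 4.92 on day 8 and 17.1 on day 21 (log2 change −5.97 ± 0.83, adjusted p = 2.19e-05). LIN28A, an RNA-binding protein of early embryonic cells, went from 2288 TPM to 1447 on day 8 and 79.2 on day 21 (−4.76 ± 0.38, adjusted p = 5.78e-08). Of 14 measured pluripotency genes 11 fell, and 11 fell when adjusted over the list alone (median log2 change −4.48, or −4.27 with genes at 0 set to their bound). The camera set test gave an adjusted p of 1.77e-06 for this list, and an adjusted p = 0.0258 with an estimated correlation. Counts of POU5F1 and NANOG can hold reads of their near-identical copies POU5F1B and NANOGP8.

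Neural progenitor and forebrain patterning genes rose in human cells in vitro. NR2F1, an orphan nuclear receptor of the developing forebrain, had no count on day 0, 188 TPM on day 8 and 165 TPM on day 21, at least 154-fold higher. FABP7, a fatty acid binding protein of radial glia, went from 48.4 TPM to 73.5 on day 8 and 1473 on day 21 (6.34 ± 1.01, adjusted p = 8.8e-05). HES5, a Notch target, was at least 27.2-fold higher on day 21. SOX2, which is shared by pluripotent and neural stem cells, did not pass the test on day 21 (0.62 ± 0.48, adjusted p = 0.333). Of 22 neural progenitor genes 17 rose, 18 when adjusted over the list alone (median 4.73, or 4.56 with bounds; camera adjusted p = 9.73e-12, and adjusted p = 0.000611 with an estimated correlation). Of 14 forebrain patterning genes 11 rose, 12 when adjusted over the list alone (median 6.74, or 4.57 with bounds; camera adjusted p = 2.08e-07, and adjusted p = 0.00363 with an estimated correlation). Among them NKX2-1 and DLX2, which mark the ventral forebrain, were at least 46.8-fold and 33.9-fold higher than on day 0.

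Neuron genes rose over the 21 days of the human culture. DCX, a microtubule protein of migrating young neurons, was at 3.24 TPM on day 0, 11.6 on day 8 and 252 on day 21 (5.80 ± 0.48, adjusted p = 8.21e-08). MAP2, a dendritic microtubule protein, was at 8.27, 320 and 537 TPM on the same days (4.94 ± 0.33, adjusted p = 6.54e-09). STMN2, a regulator of axonal microtubules, went from 2 counts on day 0 to 923 on day 21. INSM1, a transcription factor of newly formed neurons, had no count on days 0 and 8 and 66.7 TPM on day 21, at least 55-fold higher. Of 20 early neuron genes 18 rose, 19 when adjusted over the list alone (median 5.78, or 4.73 with bounds; camera adjusted p = 3.48e-13, and adjusted p = 0.0229 with an estimated correlation). Of 22 synapse genes 15 rose, 16 when adjusted over the list alone (median 2.88, or 2.35 with bounds; camera adjusted p = 1.77e-06, and adjusted p = 0.028 with an estimated correlation). SYT1, a calcium sensor of synaptic vesicles, went from 31.1 TPM to 57.6 and 74.8 (1.28 ± 0.26, adjusted p = 0.000712), and SNAP25, a vesicle fusion protein, was at least 15.4-fold higher on day 21. GFAP, an astrocyte intermediate filament, had at most 1.86 TPM up to day 21.

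Epithelial genes fell in human cells in vitro, and collagen genes of cartilage rose. CDH1, the epithelial cadherin, went from 422 TPM to 1.74 on day 8 and 6.89 on day 21 (−6.88 ± 1.26, adjusted p = 0.000326). Of 7 epithelial genes 6 fell, 6 when adjusted over the list alone (median −4.46; camera adjusted p = 8.82e-05, and adjusted p = 0.0581 with an estimated correlation). COL2A1, the main cartilage collagen, went from 16.14 TPM to 1277 on day 8 and 341 on day 21 (4.83 ± 0.66, adjusted p = 1.75e-05). Of 6 cartilage genes 4 rose, 5 when adjusted over the list alone (median 2.47; camera adjusted p = 0.00861, and adjusted p = 0.0378 with an estimated correlation). Mesenchyme and matrix genes rose by the set test (5 of 11 rose and 1 fell, the same adjusted over the list alone; median 0.93; camera adjusted p = 0.0133, and adjusted p = 0.298 with an estimated correlation). Genes of endoderm (3 of 5 fell; camera adjusted p = 0.00833, and adjusted p = 0.0641 with an estimated correlation) and endothelium (2 of 5 fell, 3 when adjusted over the list alone; camera adjusted p = 0.0191, and adjusted p = 0.059 with an estimated correlation) fell as sets. The called endoderm members included CLDN6 and EPCAM, which pluripotent cells also express.

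Other lists did not pass camera in human cells in vitro. For cell cycle genes 3 of 20 rose and 9 fell (median −0.36, adjusted p = 0.171), and MKI67, a marker of cycling cells, was at 81.7, 114 and 82.8 TPM on days 0, 8 and 21 (0.12 ± 0.24, adjusted p = 0.726). For astrocyte and radial glia genes 5 of 11 rose and 2 fell, 6 and 2 when adjusted over the list alone (median 1.99, camera adjusted p = 0.166). SLC1A2, a glutamate transporter of glia, rose (4.21 ± 0.39, adjusted p = 3.44e-07) while GJA1, a gap junction protein that is high in pluripotent cells too, fell (−3.16 ± 0.46, adjusted p = 3.74e-05). Of 13 cholesterol synthesis genes 6 rose and 1 fell (camera adjusted p = 0.181), among them HMGCS1, an early enzyme of the pathway (1.53 ± 0.27, adjusted p = 0.000218). Of 12 hypoxia and glycolysis genes 4 rose and 3 fell (camera adjusted p = 0.731), and of 15 dissociation and stress genes 2 rose and 3 fell (camera adjusted p = 0.934). For these 2 lists and for retina and oligodendrocyte genes the median and camera had opposite signs. Camera gave adjusted p-values of 0.0795 for 3 mesoderm genes, 0.0826 for 4 midbrain, hindbrain and HOX genes, 0.431 for 4 muscle genes, 0.731 for 4 neural crest genes, 0.734 for 6 oligodendrocyte genes and 0.934 for 7 retina genes. Only 1 blood gene had enough counts to be tested.

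In total 5303 of 12516 tested genes changed over days 0 to 21 in human cells in vitro (42.4%), of which 2866 rose and 2437 fell. Among genes with an average log2 CPM of at least 3, 4 of the 5 largest fitted rises on day 21 can be given as bounds, since those genes had no count on day 0. FAM198B was at least 43.2-fold higher, MMRN1 (multimerin) 94.1-fold, ANKRD1 (a transcriptional co-regulator of muscle and stretched cells) 173-fold and NR2E1 (an orphan receptor of neural stem cells) 87.9-fold. Among the largest falls were EPHA1, an ephrin receptor, and ESRP2, an epithelial splicing regulator, at least 70.3-fold and 20.5-fold lower. Of the 103 named genes called on day 21, 18 were not called without day 0 and 15 without day 21. Median changes of all genes lay between 0.00 and 0.10 on the log2 scale in the 4 courses with TMM scaling, and at 0.20 for mouse cells in vitro and 0.15 for human teratomas with DESeq2 size factors. With limma on log2(TPM + 1) they were 0.17 and 0.33 for human and mouse cells in vitro and 0.33 and 0.47 for human and mouse teratomas, and with log2(TPM + 0.1) up to 0.54.

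**Figure D1:**
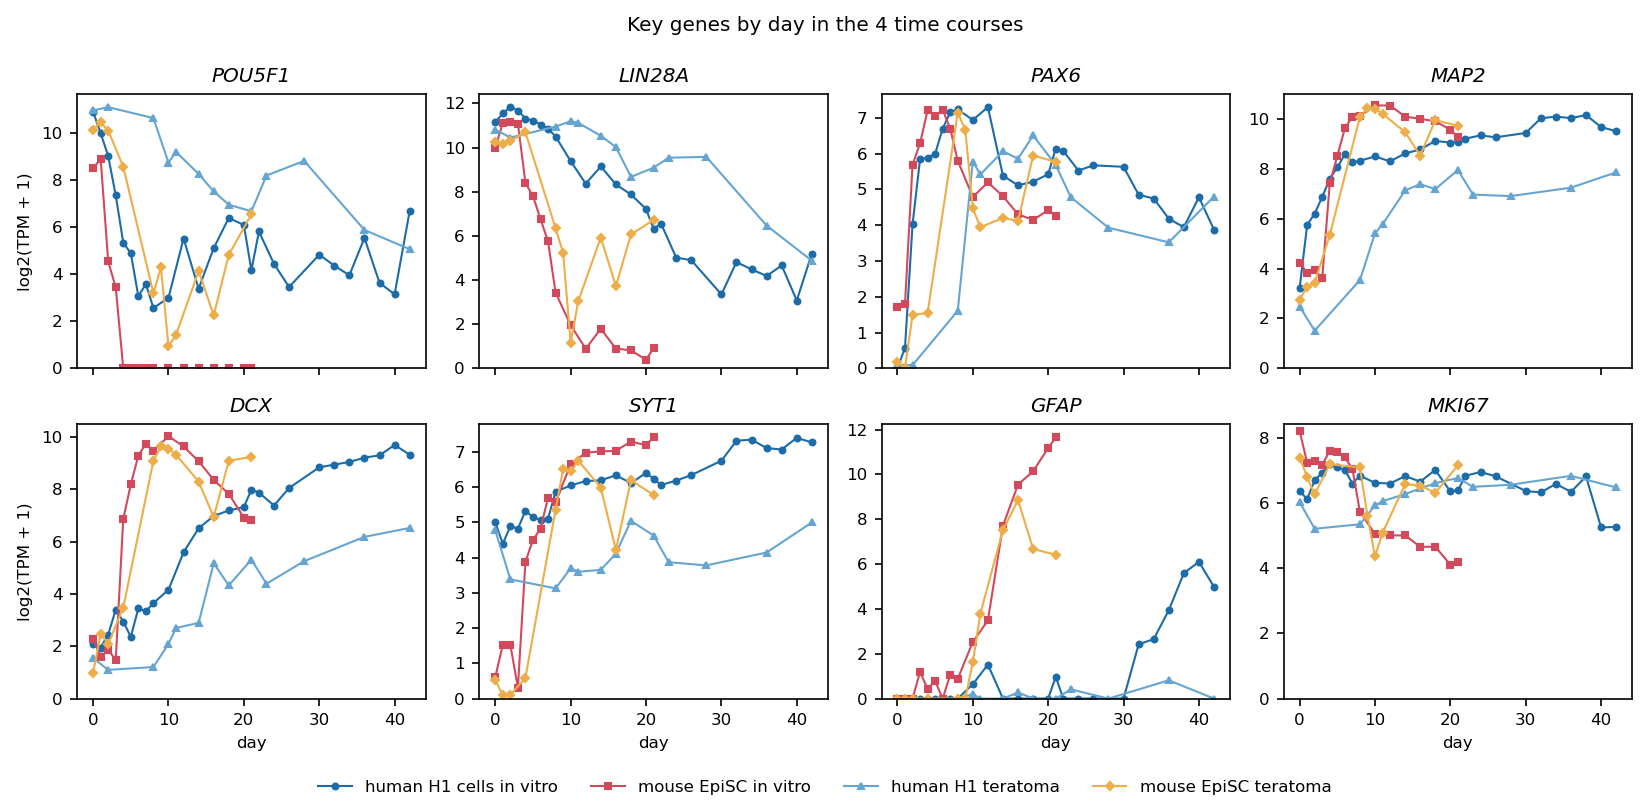
Log2(TPM + 1) of 8 key genes by day in the 4 courses, with 1 point per sampled day and no error bars because each day is 1 sample. LIN28A fell below 10 TPM by day 8 in mouse cells in vitro and was at 1447 TPM on day 8 in human cells in vitro, and GFAP reached 3216 TPM on day 21 in mouse cells in vitro and 30.6 TPM on day 42 in human cells in vitro.

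In mouse EpiSC in vitro, pluripotency genes fell and neuron, synapse and astrocyte genes rose (n = 16). The day 0 library, the baseline of this course, is the only library in vitro labelled as sorted, so changes from day 0 can also hold an effect of sorting. Pou5f1 was at 364 TPM on day 0 and had no count on days 8 and 21, at least 168-fold lower. Lin28a went from 1004 TPM to 9.79 on day 8 and 0.88 on day 21 (4223 counts to 3). Fgf5, a growth factor of the primed epiblast, went from 534 TPM to 0.46 and 1.85 (−10.20 ± 1.03, adjusted p = 5.08e-07). Of 11 pluripotency genes 9 fell, 9 when adjusted over the list alone (median −8.89, or −7.56 with bounds; camera adjusted p = 2.38e-06, and adjusted p = 0.0236 with an estimated correlation). The progenitor genes Pax6, Hes5 and Neurog2 were highest on day 6. Pax6, a transcription factor of neural progenitors, went from 2.29 TPM to 148 on day 6 and 18.09 on day 21 (2.47 ± 0.72, adjusted p = 0.00806, but −1.85 with 1 inner knot). Hes5 went from no count to 99.4 TPM on day 6 and 1.63 on day 21, and Neurog2, a proneural factor, from 1.13 to 168 and 0.93. On day 21, 6 of 21 neural progenitor genes were higher than on day 0 and 4 lower, the same adjusted over the list alone (median −0.06, camera adjusted p = 0.941).

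Mouse neuron genes had risen by day 8. Dcx went from 3.85 TPM to 710 on day 8, 1043 on day 10 and 113 on day 21 (5.76 ± 1.16 on day 21, adjusted p = 0.000513). Tubb3, a neuronal tubulin, went from 13.6 TPM to 1141 and 930 (5.89 ± 0.67, adjusted p = 1.84e-06), and Mapt, the tau protein, from 1.86 to 222 and 313 (10.75 ± 0.80, adjusted p = 2.12e-08). Of 23 early neuron genes 16 rose and 1 fell, 17 and 1 when adjusted over the list alone (median 4.61, or 4.31 with bounds; camera adjusted p = 0.000303, and adjusted p = 0.645 with an estimated correlation). All 23 tested synapse genes rose, also when adjusted over the list alone (median 7.02, or 6.09 with bounds; camera adjusted p = 1.25e-11, and adjusted p = 0.23 with an estimated correlation). Syn1, which tethers synaptic vesicles, went from 2.86 TPM to 38.0 and 82.2 (4.27 ± 0.63, adjusted p = 2.43e-05). Gad1, the enzyme that makes GABA, went from 0.99 TPM to 35.0 and 87.8 (8.06 ± 0.69, adjusted p = 8.52e-08), and Slc17a6, a vesicular glutamate transporter, was at least 155-fold higher on day 21.

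Glial genes rose in the mouse culture, Gfap and Mbp mostly after day 8 and Slc1a3 already by day 8. Gfap had no count on day 0, 0.84 TPM on day 8, 209 on day 14 and 3216 on day 21, at least 3236-fold higher. Aqp4, a water channel of astrocyte end-feet, was at least 903-fold higher. Slc1a3, a glutamate transporter of radial glia and astrocytes, went from 29.6 TPM to 183 and 560 (4.16 ± 0.54, adjusted p = 7.39e-06). Of 19 astrocyte genes 14 rose, 14 when adjusted over the list alone (median 4.16; camera adjusted p = 2.38e-06, and adjusted p = 0.0307 with an estimated correlation). Of 12 oligodendrocyte genes 7 rose, 8 when adjusted over the list alone (median 2.61; camera adjusted p = 0.0102, and adjusted p = 0.299 with an estimated correlation). Mbp, a myelin protein, went from 3.54 TPM to 9.97 and 215 (4.32 ± 0.72, adjusted p = 8.58e-05).

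Cell cycle genes fell together in mouse cells in vitro. Mki67 went from 296 TPM to 52.3 on day 8 and 17.1 on day 21 (−3.72 ± 0.40, adjusted p = 1.06e-06) and Plk1, a mitotic kinase, from 202 to 30.8 and 5.61 (−4.89 ± 0.65, adjusted p = 9.19e-06). All 20 cell cycle genes fell, also when adjusted over the list alone (median −3.40; camera adjusted p = 1.25e-11, and adjusted p = 0.189 with an estimated correlation). Of 5 epithelial genes 3 fell, 3 when adjusted over the list alone (median −3.79; camera adjusted p = 0.0388, and adjusted p = 0.296 with an estimated correlation), including Krt8, a keratin of simple epithelia (−5.61 ± 0.89, adjusted p = 5.42e-05). Dcn, a matrix proteoglycan of fibroblasts, rose from 3.56 TPM to 489 on day 21 (5.17 ± 1.02, adjusted p = 0.000412), while the 13 mesenchyme genes as a set did not pass (2 rose, camera adjusted p = 0.929). Camera gave adjusted p-values of 0.106 for cholesterol synthesis, 0.172 for muscle, 0.25 for cartilage, 0.293 for forebrain patterning, 0.432 for mesoderm, 0.624 for endothelium and for dissociation and stress, 0.772 for neural crest, 0.875 for midbrain, hindbrain and HOX, and 0.941 for retina, for hypoxia and glycolysis, and for endoderm, where median and camera had opposite signs. In total 8692 of 12893 tested genes changed (67.4%), of which 4534 rose and 4158 fell. The largest rises by the fit were Lgi3, a secreted neuronal protein, at least 77.1-fold higher, and Slc4a10, a neuronal bicarbonate transporter, Caly, Fibcd1 and Gpr22, at least 77.5-fold, 46.9-fold, 12.9-fold and 7.43-fold higher. Of the 96 named genes called on day 21, 15 were not called without day 0, 9 without day 21 and 13 with 1 inner knot.

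The courses of the species in vitro were then compared in 1 model with a course-by-day term. LIN28A, which was at 79.2 TPM in human and 0.88 TPM in mouse cells on day 21, differed with an adjusted p of 2.64e-11. The RNA-binding proteins IGF2BP1, IGF2BP2 and IGF2BP3 were at 253, 138 and 230 TPM on day 0 and 174, 273 and 176 TPM on day 21 in human cells, and at 223, 156 and 169 TPM on day 0 and 0.61, 9.2 and 3.54 TPM on day 21 in mouse cells (adjusted p = 3.13e-15, 1.13e-16 and 2.24e-15). HMGA2, a chromatin protein of proliferating embryonic cells, was at 187 and 325 TPM on days 0 and 21 in human cells and at 239 and 1.38 TPM in mouse cells (adjusted p = 9.6e-16). ATP1B1, a sodium pump subunit, went from 72.2 to 142 TPM in human cells and from 8.28 to 948 TPM in mouse cells (adjusted p = 1.05e-15). The 5 genes IGF2BP1, IGF2BP2, IGF2BP3, HMGA2 and ATP1B1 had the smallest p-values of the 10207 genes tested. Of 25 tested key genes 23 differed, including SYT1 (adjusted p = 2.64e-10), MKI67 (1.21e-09), DCX (4.53e-07) and POU5F1 (0.00469). NANOG (adjusted p = 0.461) and SOX2 (adjusted p = 0.299) did not pass. In total 5929 genes differed (58.1%). Of 3349 genes that changed in both species 2357 moved in the same direction (70.4%). If the calls were independent, 1482 of all 10207 genes tested in both species would be called in the same direction. That number also holds the chance of being called in both, so it is no baseline for the 70.4%.

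The order of events was compared by the half-change day, the first day at which a gene's smoothed log2(TPM + 1) had covered 0.5 of the way from day 0 to its extreme within 21 days. Early neuron genes passed it on day 11.9 in human and day 4.14 in mouse cells in vitro (medians of 20 genes), and the median difference was 8.06 days (−1.53 to 10.21), with 19 of 20 genes later in human cells. Synapse genes differed by a median of 6.91 days (14 genes, 11 later in human), forebrain patterning genes by 5.28 days (6 of 6 later) and astrocyte genes by 4.84 days (7 genes, 4 later). Lists with 5 genes or fewer went both ways. Later in human cells were muscle genes by 8.16 days (2 of 2 later), endothelium by 5.94 days (2 of 2 later), cell cycle by 0.971 days (3 genes, 2 later), epithelium by 0.944 days (5 genes, 3 later), and 1 gene each of the mesoderm (7.22 days) and retina lists (2.98 days). The medians below 0 were those of cartilage at −2.56 days (4 genes, 2 later), mesenchyme −3.67 days (0 of 2 later), hypoxia and glycolysis −1.69 days (2 genes), endoderm −0.858 days (2 genes), neural crest −0.302 days (2 genes), and 1 gene each of the oligodendrocyte (−6.18 days) and stress lists (−6.02 days). Pluripotency genes fell 1.63 days later (7 of 7 later) and neural progenitor genes rose 0.964 days later in human cells (12 genes, 9 later). Over all 2009 genes that moved the same way in both species the medians were 5.93 days in human and 5.38 days in mouse cells, and 54.1% of genes were later in human cells. The median difference over these genes was 0.373 days (quartiles −1.94 and 3.41), and it turned to −0.0104 without human day 21 and to −0.135 without mouse day 1. It was 0.858 without human day 1, 0.227 and 0.0979 without human days 10 and 20, and 0.124 and 0.243 without mouse days 2 and 4. It was 2.82 days when the human course was followed to day 42, and 2 days for the day of the extreme value.

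The largest delays among genes that reached 10 TPM in both species were of falling genes. MAD1L1, a mitotic checkpoint protein, fell at day 18.5 in human and day 1.98 in mouse cells, HAS2, a hyaluronan synthase, at days 18.0 and 1.74, and MESDC2, a chaperone of lipoprotein receptors, at days 18.11 and 2.60. PRR5, an mTORC2 subunit, and PSEN2, a presenilin, fell 15.1 days later in human cells. The earliest genes in human relative to mouse were SPA17 (days 2.83 and 16.6) and NR1D2, a clock repressor (days 1.99 and 15.2), which rose, and DMXL1 (days 1.64 and 14.7), which fell. A single stretching factor between the courses was also estimated from 3349 genes changed in both species, with the human course taken to day 42. The highest correlation of changes across genes and days was reached at 3.45 human days per mouse day (r = 0.477 over 10 mouse days, against 0.321 over 15 mouse days at factor 1). Over the same 9 mouse days at every factor it was highest at 3.95 (r = 0.474, against 0.238 at factor 1), close to the largest factor tried, 4. Leaving out single days gave 2.6 to 3.95, and rank correlation gave 2.6. At factor 2 the Pearson correlation was 0.445 over 15 mouse days. This correlation is across genes, which are not independent replicates, and no p-value was computed for either measure because there is 1 course per species. On simulated rising genes the half-change difference in vitro was 0.0107 days with no difference in pace, 3.80 days (87.5% later) with a factor of 2 and 4.70 days (84.6% later) with a factor of 3, against 0.373 days and 54.1% here. The simulated genes followed smooth mouse trends with the same dispersion for every gene, while 691 of the genes here fell. The 1318 genes here that rose differed by 0.295 days (53.7% later in human cells).

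**Figure D2:**
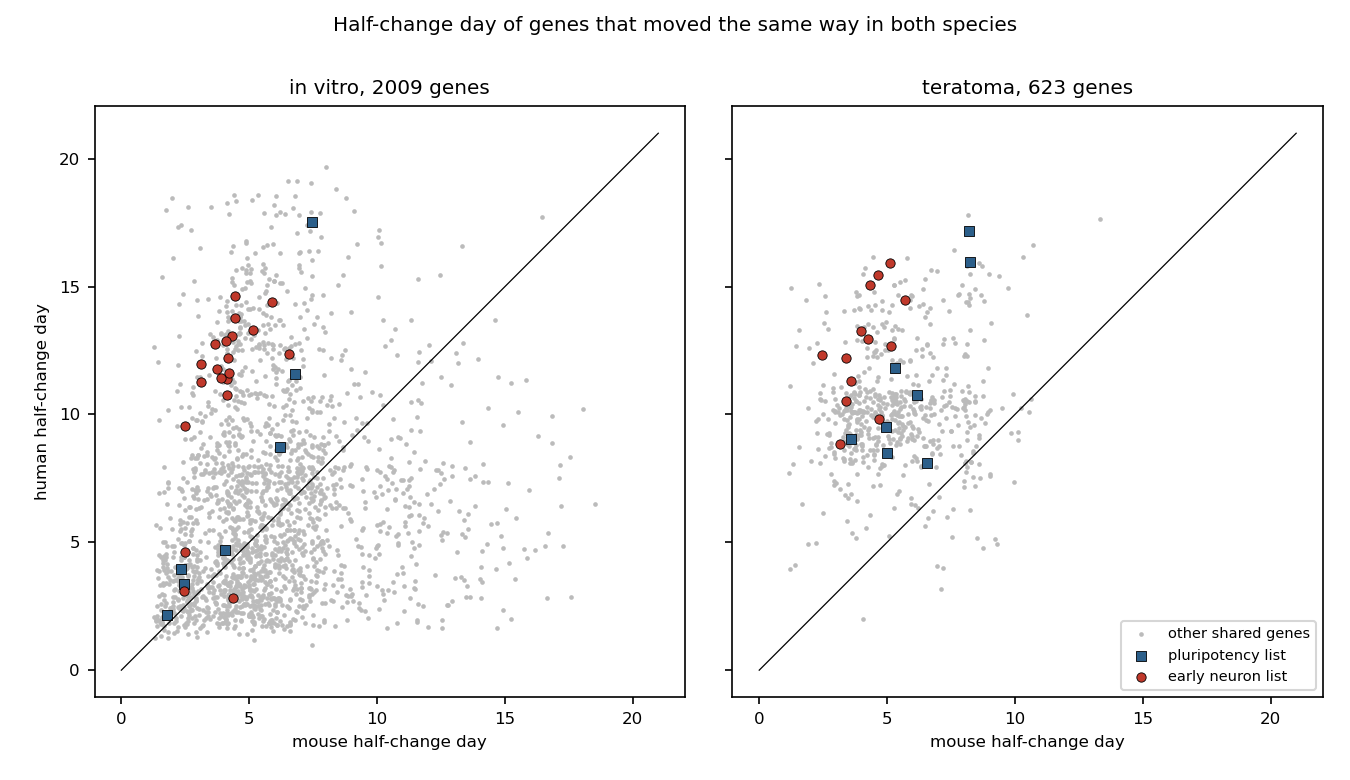
Half-change day in human (vertical axis, days) against mouse (horizontal axis, days) for the 2009 genes in vitro and 623 genes in teratomas that moved the same way in both species, with the pluripotency and early neuron lists marked and a line of equal days. In vitro 19 of 20 early neuron genes lie above the line, and in teratomas 94.5% of all genes do.

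Human cells in vitro were followed further, from day 21 to day 42 (n = 26 over the whole course). Lists were counted by their members in this comparison, without a set test. DCX went from 252 TPM to 639 (1.99 ± 0.26, adjusted p = 4.41e-06), GAD1 from 40.0 to 157 (2.17 ± 0.45, adjusted p = 0.00106) and SLC1A3 from 87.6 to 351 (2.07 ± 0.34, adjusted p = 8.8e-05). GFAP was at 0.97 TPM on day 21 (1 count), 67.6 on day 40 and 30.6 on day 42 (28 counts). HOXB8, a posterior patterning factor, had no count on day 21 and 483 TPM on day 42 (258 counts), and HOXA5 went from no count to 128 TPM. Of 22 early neuron genes 10 rose and 3 fell, of 24 synapse genes 15 rose and 1 fell, of 17 midbrain, hindbrain and HOX genes 11 rose and 1 fell, and of 16 astrocyte genes 8 rose. Of 20 cell cycle genes 17 fell, among them MKI67 (82.8 to 37.6 TPM, −1.05 ± 0.24, adjusted p = 0.00294), and of 22 neural progenitor genes 9 fell. PAX6 (69.5 to 13.6 TPM, −1.75 ± 0.51, adjusted p = 0.0156) and COL2A1 (341 to 13.9 TPM, −4.30 ± 0.55, adjusted p = 3.54e-06) were lower on day 42. DLK1, a Notch-related surface protein of progenitors, went from 1101 to 8.61 TPM (−8.35 ± 0.73, adjusted p = 7.57e-09). In total 1773 of 13086 genes changed, of which 999 rose and 774 fell.

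In human teratomas (n = 9 days to day 21) pluripotency genes fell and neural, hindbrain and cartilage genes rose, mostly after day 8. POU5F1 was at 2013 TPM on day 0, 1606 on day 8 and 102 on day 21 (−4.54 ± 0.41, adjusted p = 0.00075), and L1TD1, an RNA-binding protein of pluripotent cells, at 2403, 707 and 98.8 TPM (−4.80 ± 0.42, adjusted p = 0.000658). Of 21 pluripotency genes 9 fell; adjusted over the list alone 10 fell and 1 rose (median −2.29, or −2.83 with bounds; camera adjusted p = 1.69e-06, and adjusted p = 0.126 with an estimated correlation). ZIC1, a neural plate transcription factor, had no count on day 0 and 230 TPM on day 21, at least 3100-fold higher. LHX2, a forebrain and eye field factor, was at least 593-fold higher, and RSPO3, a Wnt agonist, at least 803-fold. SOX1, an early neuroectoderm factor, went from 2 counts on day 0 to 2120 on day 21. Of 22 neural progenitor genes 14 rose, 19 when adjusted over the list alone (median 7.70, or 6.33 with bounds; camera adjusted p = 5.03e-12, and adjusted p = 0.13 with an estimated correlation). SOX2 was at 176, 202 and 168 TPM on days 0, 8 and 21 (−0.43 ± 0.33, adjusted p = 0.491).

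Neuron and regional patterning genes rose in human teratomas. MAP2 went from 4.57 TPM to 10.6 on day 8 and 247 on day 21 (5.23 ± 0.41, adjusted p = 0.000658), STMN2 from 0.425 to 3.60 and 124 (8.27 ± 1.15, adjusted p = 0.00375) and DLL1, a Notch ligand of newborn neurons, from 0.255 on day 0 to 7.41 on day 8 (8.49 ± 0.83 on day 21, adjusted p = 0.00111). Of 22 early neuron genes 9 rose, 14 when adjusted over the list alone (median 6.84, or 6.15 with bounds; camera adjusted p = 2e-12, and adjusted p = 0.13 with an estimated correlation). Of 12 forebrain patterning genes 5 rose, 8 when adjusted over the list alone (median 8.01, or 6.95 with bounds; camera adjusted p = 2.78e-05, and adjusted p = 0.131 with an estimated correlation). EMX2, a cortical patterning factor, was at least 922-fold higher. Of 15 midbrain, hindbrain and HOX genes 5 rose, 8 when adjusted over the list alone (median 9.35, or 5.64 with bounds; camera adjusted p = 1.45e-07, and adjusted p = 0.131 with an estimated correlation), with PAX2, a midbrain-hindbrain boundary factor, at least 127-fold higher. Synapse genes (3 of 21 rose; camera adjusted p = 0.0206, and adjusted p = 0.214 with an estimated correlation) and retina genes (0 of 9 rose by edgeR, 1 at an unadjusted p under 0.05; median 4.91; camera adjusted p = 0.0164, and adjusted p = 0.214 with an estimated correlation) passed as sets.

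Some genes of the neural crest, cartilage, mesenchyme and mesoderm lists also rose in human teratomas. PAX3 and PAX7, which mark neural crest and muscle precursors, were at least 383-fold and 117-fold higher on day 21. Of 13 neural crest genes 4 rose, 4 when adjusted over the list alone (median 7.04, or 5.92 with bounds; camera adjusted p = 1.83e-05, and adjusted p = 0.214 with an estimated correlation). COL2A1 went from 12.7 TPM to 4.09 on day 8, 965 on day 18 and 381 on day 21 (5.19 ± 0.84, adjusted p = 0.00693). Of 9 cartilage genes 5 rose, 5 when adjusted over the list alone (median 2.91, or 2.81 with bounds; camera adjusted p = 0.00124, and adjusted p = 0.13 with an estimated correlation). Of 13 mesenchyme genes 6 rose and 1 fell, 7 and 1 when adjusted over the list alone (median 2.41; camera adjusted p = 0.00155, and adjusted p = 0.131 with an estimated correlation). For 10 mesoderm genes, of which 2 rose, camera gave an adjusted p of 0.00176, and an adjusted p = 0.191 with an estimated correlation. Blood genes did not pass (1 of 5 rose, camera adjusted p = 0.238), and the member that rose was HBE1, the embryonic beta-like globin, with no count on day 0 and 267 TPM on day 21.

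Dissociation and stress genes rose in the human teratomas beside the groups above. FOS and EGR1, immediate early genes that tissue digestion also induces, went from 16.6 TPM to 898 (6.12 ± 0.87, adjusted p = 0.00407) and from 8.27 TPM to 652 on day 21 (6.65 ± 1.02, adjusted p = 0.00553). Of 16 stress genes 5 rose and 1 fell, 8 and 2 when adjusted over the list alone (median 2.13; camera adjusted p = 0.00289, and adjusted p = 0.22 with an estimated correlation). Cholesterol synthesis genes fell (8 of 13, 12 of 13 when adjusted over the list alone; median −1.59; camera adjusted p = 1.07e-06, and adjusted p = 0.214 with an estimated correlation), and HMGCS1 went from 916 TPM to 182 on day 8 and 382 on day 21 (−1.68 ± 0.38, adjusted p = 0.0255), with a change of 0.06 when day 0 was left out. Cell cycle genes fell as a set (3 of 20 fell; adjusted over the list alone 9 fell and 1 rose; median −0.62; camera adjusted p = 0.00155, and adjusted p = 0.131 with an estimated correlation), while MKI67 was at 64.4 and 108 TPM on days 0 and 21 (0.47 ± 0.19, adjusted p = 0.180). Epithelial genes fell (3 of 8, 5 when adjusted over the list alone; median −2.28; camera adjusted p = 0.00129, and adjusted p = 0.214 with an estimated correlation), with KRT18, a keratin of simple epithelia, at 401 and 88.1 TPM (−2.68 ± 0.35, adjusted p = 0.00293). Camera gave adjusted p-values of 0.122 for astrocyte genes, 0.152 for hypoxia and glycolysis, 0.203 for endoderm, 0.26 for oligodendrocyte genes, 0.582 for muscle and 0.859 for endothelium.

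In total 2118 of 14311 tested genes changed in human teratomas (14.8%), of which 1050 rose and 1068 fell. With limma on log2(TPM + 1) the share of calls that rose was 67.7%, against 49.6% here. The count was 3233 with DESeq2's likelihood ratio test, 1408 without day 16 and 6944 with the repeat columns of a day kept as separate libraries. On day 8 only 29 genes were higher and 19 lower than on day 0. Of the 79 named genes called on day 21, 59 were not called without day 0, 36 without day 21, 16 without day 11 and 15 with limma.

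In mouse teratomas (n = 12 days) pluripotency genes had fallen and neuron genes had risen by day 8. Pou5f1 went from 1141 TPM to 8.19 on day 8 (−6.72 ± 1.07, adjusted p = 0.00167) and 93.2 on day 21 (adjusted p = 0.0539), and Nanog, a core pluripotency factor, from 690 to 17.6 and 32.7 (−4.68 ± 0.32 on day 21, adjusted p = 4.62e-05). Of 18 pluripotency genes 8 fell and 1 rose, 11 and 1 when adjusted over the list alone (median −4.03; camera adjusted p = 1.48e-06, and adjusted p = 0.338 with an estimated correlation). Fabp7 went from 4.46 TPM to 351 and 1034 (7.02 ± 0.89, adjusted p = 0.000899). Of 21 neural progenitor genes 13 rose; adjusted over the list alone 14 rose and 1 fell (median 4.17, or 3.40 with bounds; camera adjusted p = 5.92e-06, and adjusted p = 0.338 with an estimated correlation). Of 15 forebrain patterning genes 14 rose, 15 when adjusted over the list alone (median 10.8, or 7.19 with bounds; camera adjusted p = 6.31e-08, and adjusted p = 0.338 with an estimated correlation). Dlx1, a transcription factor of forebrain interneurons, was at least 959-fold higher. Of 19 midbrain, hindbrain and HOX genes 9 rose, 13 when adjusted over the list alone (median 4.61, or 2.82 with bounds; camera adjusted p = 4.4e-05, and adjusted p = 0.169 with an estimated correlation).

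Dcx was at 0.97 TPM on day 0, 545 on day 8, 794 on day 9 and 601 on day 21 in mouse teratomas (8.36 ± 1.29, adjusted p = 0.00206), and Map2 at 5.73, 1080 and 848 TPM on days 0, 8 and 21 (6.78 ± 0.97, adjusted p = 0.00154). Of 23 early neuron genes 17 rose, 19 when adjusted over the list alone (median 6.82, or 6.10 with bounds; camera adjusted p = 1.09e-08, and adjusted p = 0.40 with an estimated correlation). Of 24 synapse genes 18 rose, 21 when adjusted over the list alone (median 4.86; camera adjusted p = 1.19e-08, and adjusted p = 0.40 with an estimated correlation). Gria2, a glutamate receptor subunit, and Slc32a1, the vesicular GABA transporter, were at least 680-fold and 106-fold higher on day 21, and Gad1 went from 2 counts to 1165. Gfap had no count on days 0 and 8 and was at 461 TPM on day 16 and 84.5 on day 21, and Slc1a2 went from 0.72 TPM to 77.2 and 81.7 (8.03 ± 0.70, adjusted p = 0.000157). Of 19 astrocyte genes 8 rose, 8 when adjusted over the list alone (median 2.63, or 3.57 with bounds; camera adjusted p = 0.000336, and adjusted p = 0.485 with an estimated correlation). Of 13 oligodendrocyte genes 5 rose, 6 when adjusted over the list alone (median 4.62; camera adjusted p = 0.000217, and adjusted p = 0.455 with an estimated correlation), with Mbp at 2.8, 10.8 and 324 TPM (6.42 ± 1.13, adjusted p = 0.00383).

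Markers of other tissues varied strongly between mouse teratoma days. Col1a1, the main collagen of connective tissue, was at 31.3 TPM on day 0, 13635 on day 16 and 1434 on day 21 (adjusted p = 0.209), and all 13 mesenchyme genes were highest on day 16. The mesenchyme list (0 of 13 rose by edgeR, also when adjusted over the list alone, and 2 at an unadjusted p under 0.05; median 3.28; camera adjusted p = 0.0178, and adjusted p = 0.60 with an estimated correlation), endothelium (1 of 11 rose; camera adjusted p = 0.00369, and adjusted p = 0.496 with an estimated correlation), blood (0 of 11 rose, also when adjusted over the list alone, and 2 at an unadjusted p under 0.05; median 2.47, or 2.39 with bounds; camera adjusted p = 0.00248, and adjusted p = 0.485 with an estimated correlation) and cartilage (3 of 8 rose; camera adjusted p = 0.00744, and adjusted p = 0.485 with an estimated correlation) passed camera upwards. Cell cycle genes (0 of 20 fell by edgeR, also when adjusted over the list alone, and 7 at an unadjusted p under 0.05; median −1.50; camera adjusted p = 0.00133, and adjusted p = 0.584 with an estimated correlation) and cholesterol synthesis genes (3 of 13 fell, 5 when adjusted over the list alone; median −1.15; camera adjusted p = 0.00121, and adjusted p = 0.485 with an estimated correlation) passed camera downwards. Idi1, an isomerase of the cholesterol pathway, went from 404 TPM to 61.4 on day 21 (−2.76 ± 0.54, adjusted p = 0.00599). The cholesterol list median was 209 TPM on day 0, 88.4 on day 1, 97.3 on day 8 and 81.05 on day 21, so it fell mostly by day 1. The stress list median went from 13.0 TPM on day 0 to 63.1 on day 1 and 113 on day 21. An effect of the day 0 baseline was not tested. Camera gave adjusted p-values of 0.0713 for retina, for dissociation and stress, and for hypoxia and glycolysis, 0.209 for neural crest, 0.66 for epithelium, 0.831 for muscle, 0.939 for endoderm and 0.968 for mesoderm, and for endoderm and epithelium the median and camera had opposite signs. These set tests compare day 21 with day 0 only. On days 0, 2 and 4 the endoderm median was 0.385, 15.0 and 0.8425 TPM and the mesoderm median 0.775, 6.34 and 1.04 TPM. The epithelial median was 1.195, 10.5 and 1.27 TPM. Over the whole course 5 of 10 endoderm, 7 of 10 mesoderm and 7 of 10 epithelial genes were called changed. So were 12 of 13 hypoxia and 18 of 20 cell cycle genes. Of the stress genes 3 of 16 rose, among them Egr1, from 13.9 TPM to 1380 (4.24 ± 0.97, adjusted p = 0.0125). Without day 16 the same number of lists passed (14), with 19 of 23 early neuron genes rising. In total 5785 of 14078 genes changed (41.1%), of which 3007 rose and 2778 fell, and with limma on log2(TPM + 1) the share that rose was 73.2%, against 52.0% here. Of the 69 named genes called on day 21, 45 were not called without day 21, 26 without day 0 and 15 without day 1.

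**Figure D3:**
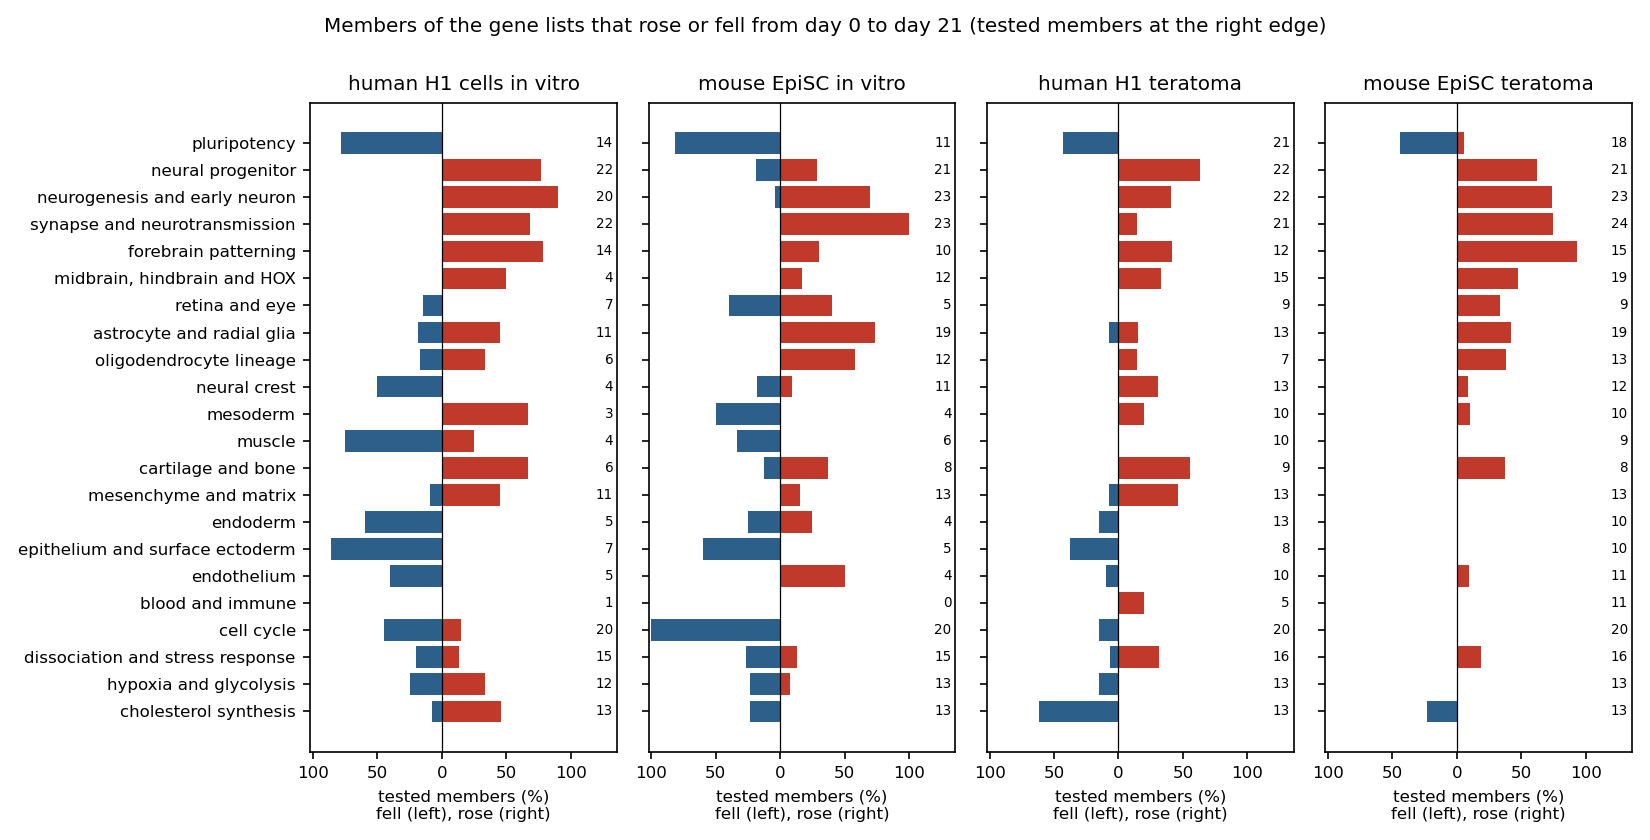
Percent of the tested members of each of the 22 gene lists that were lower (bars to the left) or higher (bars to the right) on day 21 than on day 0 by edgeR at an adjusted p under 0.05, for the 4 courses, with the number of tested members at the right edge. All 20 cell cycle genes were lower in mouse cells in vitro, and 3 of 20 in human teratomas.

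The teratoma courses of the species were compared in the same way. SCG2, a protein of secretory granules, was at 0, 102 and 71.2 TPM on days 0, 8 and 21 in mouse and at 12.0, 0.935 and 6.25 TPM in human teratomas (adjusted p = 3.3e-06), and SCG3 at 0.31, 265 and 272 TPM in mouse and at 151, 59.4 and 35.6 TPM in human teratomas (adjusted p = 4.67e-06). PTPRZ1, a receptor phosphatase of radial glia, went from 0.69 TPM to 269 on day 21 in mouse and from 167 to 191 in human teratomas, CNTFR, a cytokine receptor of neural cells, from 74.9 to 56.4 in mouse and from no count to 77.0 in human (both 3.3e-06), and CNTN1, an axonal adhesion protein, from 0.49 to 85.5 in mouse and from 10.4 to 2.74 in human (4.88e-06). Of 24 tested key genes 17 differed, including NANOG (0.000122), COL2A1 (0.000781), FABP7 (0.00109), DCX (0.00207) and TUBB3 (0.00329). PAX6 (0.0661) and MKI67 (0.12) did not pass. On simulated data this comparison recovered 6.1% of log2 differences of 2 and 52.3% of 4, so genes that did not pass may still differ. In total 2908 of 11483 genes differed (25.3%), and 6298 with the repeat columns kept separate. Of 1104 genes changed in both species 902 moved in the same direction (81.7%). With independent calls, 407 of all 11484 genes tested in each course alone would be called in the same direction. That is no baseline for the 81.7%.

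Genes that moved the same way in both teratoma courses did so later in human teratomas. Early neuron genes reached the half-change on day 12.7 in human and day 4.24 in mouse teratomas (13 genes, median difference 8.78 days, 13 of 13 later). Neural progenitor genes differed by 5.64 days (12 genes, 11 later), pluripotency genes by 5.02 days (8 of 8 later), forebrain patterning genes by 5.2 days (7 genes, 6 later) and synapse genes by 6.17 days (4 of 4 later). Of lists with 3 genes or fewer, epithelial genes differed by 1.01 days (3 genes, 2 later) and 10 more lists by 3.45 to 7.89 days with every gene later, and 1 gene each of the mesenchyme (−4.37 days) and cholesterol synthesis lists (−3.94 days) was earlier in human teratomas. These 10 lists are not independent: the oligodendrocyte and mesoderm lists held the same 1 gene (3.45 days), and the astrocyte and cartilage lists shared 1 gene (6.31 days). The latest were FBXO2 (a ubiquitin ligase subunit, day 14.9 against 1.23) and PCDH1 (a protocadherin, day 15.1 against 2.35), which fell, and JUN (day 14.5 against 1.84), NRP1 (a semaphorin receptor, day 14.7 against 2.58) and CRABP1 (a retinoic acid binding protein, day 13.3 against 1.56), which rose. COL3A1, a collagen of soft connective tissue (day 4.92 against 9.29), ZBTB4 (5.12 against 9.22) and RAI14 (4.78 against 8.75) were earliest in human relative to mouse. Over all 623 genes the medians were 10.15 and 5.21 days, the difference was 5.19 days (quartiles 3.26 and 6.78), and 94.5% of genes were later in human teratomas. Days 1, 4 and 9 were sampled only in mouse and day 23 and later only in human teratomas. With no difference in pace, simulated rising genes on these days gave 1.09 days and 73.0% later, and on the days sampled in both species the difference was 4.55 days. The correlation of changes was highest at 3.8 human days per mouse day (r = 0.664 over 7 mouse days, against 0.508 over 11 at factor 1), near the largest factor tried, 4. At factor 2 r was 0.649 over 11 mouse days, so the values at 2 and 3.8 were close, over unlike mouse days. Over the same 6 mouse days at every factor r was highest at 4 (r = 0.654, against 0.377 at factor 1). The best factor was 2.3 without mouse day 10, without mouse day 11 and with all expressed genes.

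**Figure D4:**
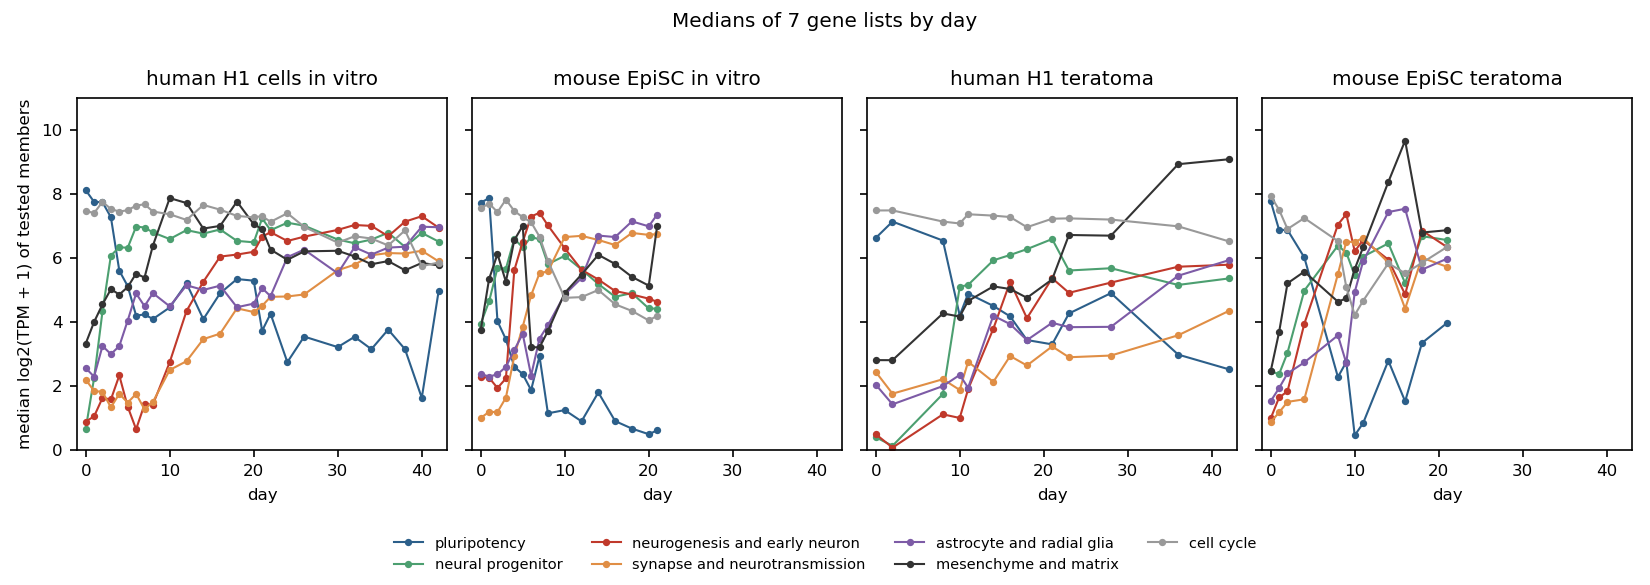
Median log2(TPM + 1) of the tested members of 7 gene lists by day in the 4 courses, with 1 point per sampled day and no error bars. The early neuron median in mouse teratomas was 60.3 TPM on day 14, 27.9 TPM on day 16 and 114 TPM on day 18, and the mesenchyme median 329, 807 and 109 TPM.

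From day 21 to day 42 connective tissue and cartilage genes rose in the counts of human teratomas (n = 13 days over the whole course). Whether reads of host cells add to these counts was not tested. COL1A1 went from 68.9 to 3177 TPM (4.32 ± 0.69, adjusted p = 0.00605) and COL2A1 from 381 to 2861 TPM (2.44 ± 0.54, adjusted p = 0.0265). ACAN, the main cartilage proteoglycan, went from 0.67 to 110 TPM (7.59 ± 1.07, adjusted p = 0.0033), OGN, a small matrix proteoglycan, from 0.24 to 607 TPM (10.78 ± 1.52, adjusted p = 0.0033) and MYH11, the smooth muscle myosin, from 0.14 to 18.4 TPM (8.89 ± 1.52, adjusted p = 0.00793). Of 13 mesenchyme genes 9 rose, of 9 cartilage genes 6 rose, and of 20 cell cycle genes 5 fell. LIN28A went from 542 to 28.4 TPM (−5.0 ± 0.86, adjusted p = 0.0084), KRT8 from 356 to 98.8 (−2.34 ± 0.33, adjusted p = 0.0033) and SOX2 was also lower than the 168 TPM of day 21 (−1.80 ± 0.36, adjusted p = 0.0172), while DCX (adjusted p = 0.104) and POU5F1 (adjusted p = 0.0775) did not pass. In total 481 of 14827 genes changed, of which 275 rose and 206 fell. This count rests on single late days: it was 13 without day 42, 200 without day 36, 238 without day 23 and 290 without day 28, and it was 852 with DESeq2's Wald test, 319 with 2 inner knots and 1180 with the repeat columns kept separate.

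Within human cells, genes that moved the same way in both settings did so later in teratomas than in culture. The day 0 libraries of the 2 settings differed by 11.6 times the variance of counting noise. The titles name the cells H1Rosa7 in vitro and not in the teratomas, so a difference between sublines of H1 stays open. MAP2 was at 320 TPM on day 8 in vitro and at 10.6 in the teratoma, and NR2F1 at 188 and 0.25 TPM (both adjusted p = 2.0e-06 for the difference of the courses). PMAIP1, a pro-apoptotic BCL2 family gene, was at 9.09 TPM on day 8 in vitro and at 435 in the teratoma (7.76e-07), MMRN1 at 269 and 0 TPM (9.14e-07), and PAK1, a kinase of the cytoskeleton, at 80.4 and 105 TPM (9.94e-07). Of 24 tested key genes 16 differed, including COL2A1 (6.09e-06), SOX1 (1.69e-05), POU5F1 (4.55e-05) and LIN28A (0.000581), and DCX (0.194) and STMN2 (0.477) did not pass. In total 2274 of 12431 genes differed (18.3%), and 4734 with the repeat columns kept separate. Of 1636 genes that changed in both settings 1460 moved in the same direction (89.2%). With independent calls, 435 of all 12431 genes tested in both settings would be called in the same direction, which is no baseline for the 89.2%. The half-change came a median of 6.40 days later in the teratoma (1190 genes, 94.6% later), and 4.01 days later on the days sampled in both settings.

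Within mouse cells, the courses of Epha4, Neurog2 and Gfap differed between the settings. The day 0 libraries of the 2 settings differed by 33.5 times the variance of counting noise. Epha4, a guidance receptor, was at 18.4 TPM on day 21 in vitro and at 131 in the teratoma, Tox3 at 11.6 and 56.8 TPM, Cecr2, a chromatin remodeller, at 1.44 and 20.1 TPM and Ttll4, a tubulin-modifying enzyme, at 6.17 and 29.2 TPM (adjusted p = 0.000118 for each). Of 27 tested key genes 13 differed, including Neurog2 (0.0013), Gfap (0.00394) and Mki67 (0.00774), and Dcx (0.282), Map2 (0.867) and Tubb3 (0.887) did not pass. In total 1803 of 12774 genes differed, and 1189 when day 21 of the teratomas was left out. Of 4630 genes changed in both settings 4459 moved in the same direction (96.3%). With independent calls, 1846 of all 12774 genes tested in both settings would be called in the same direction, which is no baseline for the 96.3%. The half-change came a median of 0.553 days later in the teratoma (3748 genes, 62.9% later), and 0.0719 days later on the days sampled in both settings.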

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

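The tests of the shared delay of rising genes, of the days sampled in both species, of the day 16 teratoma and all splits and shuffles were chosen after the result was seen, while the tests of depth and smoothing were chosen before. The counts and genes in this paragraph were picked out because the course over days differed between groups by a test of the difference itself. The delays and the day 16 teratoma described further below had no such test. Between the species in vitro 5929 genes and 23 of the tested key genes differed, in teratomas 2908 genes and 17 key genes. Between in vitro and teratoma 2274 genes and 16 key genes differed in human cells, and 1803 genes and 13 key genes in mouse cells. These counts do not rank the differences, since the power of the comparisons differed. On simulated data a log2 difference of 2 was recovered for 43.1% of genes between the species in vitro and 6.1% in teratomas. Between the settings it was recovered for 24.2% in human and 16.9% in mouse cells. The smallest adjusted p-values by edgeR in vitro between species were those of IGF2BP2 (1.13e-16), HMGA2 (9.6e-16), ATP1B1 (1.05e-15), IGF2BP3 (2.24e-15) and IGF2BP1 (3.13e-15). In teratomas between species they were those of SCG2, CNTFR and PTPRZ1 (3.3e-06 each), SCG3 (4.67e-06) and CNTN1 (4.88e-06). Between the human settings they were those of PMAIP1 (7.76e-07), MMRN1 (9.14e-07), PAK1 (9.94e-07), NR2F1 and MAP2 (2.0e-06 each), and between the mouse settings those of EPHA4, CECR2, TTLL4 and TOX3 (0.000118 each).

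The labels of days within a course, and of courses within a pair, were shuffled, with genes counted by limma and not by edgeR. In each of the 8 comparisons 1 of the 100 splits, the real one, gave as many genes. The counts thus depend on the order of days and on the course labels. Whether chance gave them cannot be decided this way. Days of 1 course follow a trend and are not exchangeable, and labels of single courses cannot be shuffled like those of replicates. With limma the real counts and the highest of the other splits were 5984 and 300 for the species in vitro, 3072 and 491 for the species in teratomas, 1941 and 410 for the human settings and 1470 and 599 for the mouse settings. With days shuffled within a course they were 5444 and 1044 for human cells in vitro, 8840 and 3973 for mouse cells in vitro, 2583 and 564 for human teratomas, and 6202 and 1329 for mouse teratomas. Since 1 course per species and setting was analysed, a difference between species or settings also holds any difference between single runs.

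Early neuron genes passed the midpoint of their rise a median of 8.06 days later in human than in mouse cells in vitro. Thinning the in vitro libraries of days 0 to 21 to their lowest total, 1.43 M counts, left a median of 8.02 days (7.73 to 8.31 over 20 draws), and omitting the running mean left 7.37 days, which argues against depth and smoothing as the whole cause. A delay shared by all rising genes is argued against by 10000 random lists of rising genes with like mouse days. Of these 100% lay below the list (random median 1.48 days, highest 6.48 days). This share may overstate the support, since members of the list move together (estimated correlation 0.224 in human and 0.542 in mouse cells in vitro) and random genes need not. The list also had the largest median delay among lists of more than 5 genes. A slower human program of neuron formation stays open as a hypothesis, as do differences between the cell lines or between single runs, which were not tested.

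Genes that moved the same way in both teratoma courses did so a median of 5.19 days later in human teratomas. On the days sampled in both species the median was 4.55 days, and after thinning to 4.69 M counts it was 5.09 days (5.01 to 5.16), which argues against uneven days and depth as the whole cause. Simulated rising genes with no difference in pace gave 1.09 days on these days, so part of the difference may come from the sampling, as the lower value on shared days also shows. A species difference in pace, tumour growth and the share of cells that differentiate stay open and were not tested.

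In the mouse teratoma of day 16 all 13 mesenchyme genes were highest (median 329, 807 and 109 TPM on days 14, 16 and 18), and none of the 23 early neuron genes was. Only days 10 and 14 had a lower total than day 16 (4.69 and 5.55 M against 5.80 M counts). Their mesenchyme medians were 49.1 and 329 TPM, at most 0.408 of that of day 16. Day 14 was itself higher in these genes than every day but day 16, so this comparison cannot decide on depth. Blood and endothelium markers were highest on day 16 as well, 22 of 25 (median 31.0 TPM, against 10.0 and 7.97), with Col1a1 at 13635 TPM, C1qa at 265 and Csf1r at 103. Cells of the host cannot be told apart from graft-derived mesenchyme, blood and endothelium, since both may carry these markers, and the sort for EGFP would remove host cells only as far as it was pure. A larger share of connective tissue in this 1 sample stays open and was not tested.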

How the results depend on the processing

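The repeat columns kept separate, shared days between the species, mouse days to 10 at every factor, and mouse teratoma day 16 left out were chosen after the data were seen, and the other alternatives before. Of 85 counts under named alternatives 69 stayed within 1.5 times and 16 moved, and of 198 with 1 day left out 192 stayed and 6 moved. Of 32 times and factors under named alternatives 25 stayed within 1.5 times and 7 did not. With 1 day left out 66 of 75 did and 9 did not, 2 of them with the other sign. Of 194 list results 140 kept their side of the threshold, 43 lost it and 11 gained it, and 0 of those past it in either setting changed direction. Lists past it in neither setting were not counted for direction. Some of them turned, for example neural progenitor genes in mouse cells in vitro (lower by camera, higher by fry). Named genes were checked only with DESeq2 size factors, limma on log2(TPM + 1), 1 inner knot at day 8 and each day left out. Of the 347 named genes called on day 21 over the 4 courses, 173 were called in the same direction in all of these alternatives. Of the others, 171 were lost in at least 1, and 10 turned direction in at least 1. Of the 59 uncalled 29 were called in at least 1.

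The count of changed genes in human teratomas (2118) was 3233 with the DESeq2 likelihood ratio test (2085 of them shared), 6944 with the repeat columns kept separate (2086 shared) and 6700 with a replicate block, and 1408 (without day 16) to 2782 (without day 0) with 1 day left out. From day 21 to 42 in human teratomas (481) it was 852 with the DESeq2 Wald test, 319 with inner knots at days 8 and 21, 1180 with separate columns, 984 with the replicate block and 13 (without day 42) to 697 with 1 day left out. Between the species in teratomas (2908) it was 6298 with separate columns and 6126 with the replicate block, and between the human settings (2274) 4734 and 4624. Separate columns treat the near-identical columns of 1 day as independent samples. For the other moved counts the cause was not tested. Columns with the same repeat number did not deviate together (correlations −0.019 to 0.026 over 28 human pairs of days, 0.012 to 0.021 over 3 mouse pairs, 0 of them above 0.1), so the numbers do not pair the samples. Between the mouse settings (1803) leaving out 1 day gave 1189 to 2216. The other counts stayed within 1.5 times of theirs with 1 day left out: 4867 to 5384 and 8216 to 8795 for human and mouse cells in vitro, 4636 to 6003 for mouse teratomas, 1217 to 2034 from day 21 to 42 in vitro, 5723 to 6025 and 2326 to 3259 between species in vitro and in teratomas, and 1786 to 3226 between the human settings.

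The half-change difference in vitro (0.373 days) was 2 days for the day of the extreme, 2.82 with the whole human course, and −0.135 (without mouse day 1) to 0.858 (without human day 1) with 1 day left out, also below 0 without human day 21 (−0.0104). In teratomas (5.19 days) it was 4.34 without the running mean, 6.02 on the spline curve, 8 for the day of the extreme, 6.10 with the whole human course, 4.55 on shared days and 4.65 to 5.92 with 1 day left out. The time factor in teratomas (3.8) was 2.3 with all expressed genes, 3.9 with the root mean square difference and 4 with mouse days to 10 at every factor. With 1 day left out it was 2.3 (without mouse day 10 or 11) to 3.8. In vitro (3.45) it was 2.6 with rank correlation, and 2.6 to 3.95 with 1 day left out. Within species, on shared days, the difference of the settings was 4.01 days for human (6.40 on all days) and 0.0719 for mouse (0.553). The factor is bounded at 4, the largest tried.

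The number of lists past the threshold with an estimated correlation was 6 in place of 10 in human and 2 in place of 7 in mouse cells in vitro, and with camera 0 in place of 15 and 14 in human and mouse teratomas, where 8 and 1 lists had an unadjusted p under 0.05 and fry called 15 and 11. This correlation is taken from the residuals of 9 to 16 days. With fry, which tests a list's own direction, it was 14 in human and 12 in mouse cells in vitro. Day 21 changes turned with 1 inner knot at day 8 for MBP (0.17, main −1.92) and PMAIP1 (0.76, main −2.68) in human and Hes5 (−0.22, main 5.12), Hoxa2 (−0.59, main 3.36), Neurog2 (−4.74, main 3.73) and Pax6 (−1.85, main 2.47) in mouse cells in vitro. Pax7 in mouse cells in vitro (main −6.58) was 0.31 with limma on log2(TPM + 1) and −8.67 to 1.88 with 1 day left out. Leaving out 1 day, the range was −1.96 to 0.052 for IER2 in human cells in vitro, and −13.86 to 11.21 for EN2, −3.59 to 0.52 for FDFT1 and −2.92 to 0.058 for HMGCS1 in human teratomas. The turn came in each case without day 0, where the fitted value of day 0 is extrapolated from later days. For the genes that turned with the knot the cause was not tested. The lowest total of a library was 0.909 M counts, on day 42 of human cells in vitro.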

Other observations

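The genes below were chosen after their values were seen, and they describe single days with 1 sample each, without a test unless one is named. In mouse teratomas, simple epithelial keratin Krt8 was at 31.5 TPM on day 0, 192 on day 1, 715 on day 2 and 4.19 on day 8, while in mouse cells in vitro it went from 151 TPM on day 0 to 3.60 on day 4. In human cells in vitro, RAX, a transcription factor of the eye field and hypothalamus, was at 0.33 TPM on day 0, 76.7 on day 3, 81.2 on day 4 and 14.6 on day 10, and in human teratomas it was at 32.0 TPM on day 10 and 109 on day 18. Rax was at most 0.58 TPM in mouse cells in vitro and 1.71 TPM in mouse teratomas. Ttr, a carrier protein of the choroid plexus and of liver and yolk sac, was at 1.24 TPM on day 12, 290 on day 14 and 662 on day 21 in mouse cells in vitro, and TTR had no count on any of the 26 days of human cells in vitro.

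In human teratomas HBE1, the embryonic globin, was at 27.1 TPM on day 18, 267 on day 21, 4538 on day 23, 429 on day 28 and 2890 on day 42. Whether reads of host cells add to these values was not tested. Endoderm genes did not pass as a set on day 21 (camera adjusted p = 0.203). AFP, a plasma protein of yolk sac and fetal liver, was at 2.29 TPM on day 18, 62.7 on day 21, 164 on day 23 and 40.9 on day 42 (adjusted p = 0.828 between days 21 and 42), and TTR at 31.1 TPM on day 21 and 250 on day 36. POU5F1 was at 102 TPM on day 21, 294 on day 23 and 454 on day 28.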
